A study of Mus musculus with 6 samples.

How the data were processed

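Regulatory T cells from mouse spleen and peripheral lymph nodes had been sorted, RNA had been extracted with a column kit for small samples, and libraries had been made with the NEBNext Ultra II RNA kit and sequenced on a NextSeq500, per the labels' protocols. The labels state no unique molecular identifiers and no strand setting. HISAT2, HTSeq and DESeq2 are named, with the mm10 genome, per the submitters' processing notes; their versions, the annotation and the counting mode are not given in the sources used here. Because strand use is unknown, reads of a gene and of an antisense or overlapping neighbour cannot be told apart.

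The authors deposited 3 tables. The first holds whole-number read counts per gene for 6 libraries, as deposited by the authors and not normalized. The second holds WT and KO libraries only, with values that the authors divided by size factors, so its unit is a normalized signal per gene. The third holds the authors' comparison of KO with WT, with a mean signal, a log2 fold change and its standard error, a test score, and p-values with adjusted p-values, per the file headers. Those fold changes and p-values in the authors' deposited table are quoted as theirs. In the second table every value above 0 was a whole multiple of the value of 1 read in its library (100% of values in each of the 4 libraries, tolerance 0.02 reads), so whole reads were recovered and tested as an added alternative, in which edgeR called 12 genes. All comparisons were made within a table, since the tables hold different values under the same library names. No column of per-sample values was left unused.

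Samples were placed in groups by the genotype and condition in their labels: WT, KO and KO EAE at 2 libraries each. Of 24449 deposited rows in the count table, 25 whose name was a number or a date were left out because they name no gene (at most 0.217% of the reads of a library); in the normalized table this was so for 27 of 23420 rows (at most 0.284%). That left 24424 and 23393 genes, of which 913 and 7665 had no read in any library. Neither table had a gene named as mitochondrial. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 18.8 in WT, 22.0 in KO and 36.5 in KO EAE in the count table and of 29.3 and 26.1 in the normalized table, so each library counted as 1 replicate. The biological coefficient of variation was 0.178 in the count table and 0.291 in the normalized table. Gene identifiers, chromosomes and positions came from GENCODE M21 (mm10), matched by gene symbol, and are 1-based.

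Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10, minimum total count 15), TMM normalization, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment over the 14548 genes tested and a threshold of 0.05. All 6 libraries were fitted with 1 coefficient per group and no block, so that the groups shared 1 estimate of the spread over 3 residual degrees of freedom. The comparisons were KO against WT, KO EAE against KO, and KO EAE against WT. Levels are counts-per-million (CPM), after TMM scaling for the genes named by the rule and for all means and standard deviations and before it for Mki67, Ifit3, Xist and genes named only in the closing observations, and 3 reads were taken as the floor of a library. Floors cover counting error only, since reads were not tied to single molecules. Adjusted p-values are from this test unless another is named, and p-values of lists come from camera. The SE after an edgeR log2 change is approximate: the size of the change divided by the square root of its F statistic.

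The design, the tests, the gene lists, the rule for naming genes and the main alternatives were set before the data were examined. The 25 lists tested were the regulatory T cell signature, effector regulatory T cells, naive and central cells, Th1, Th2, Th17, follicular (Tfh and Tfr), T cell identity, early receptor response, cell cycle, type I interferon response, homing receptors, NK and cytotoxic genes, CD8 lineage, interleukin-2, STAT5 and cytokine signals, apoptosis and survival, glycolysis, oxidative phosphorylation, cholesterol synthesis, and markers of B cells, plasma cells, myeloid and dendritic cells, MHC class II presentation, erythroid cells, and stromal and endothelial cells. A list of sex-linked genes served as a sample check only. Of the list genes, 431 matched by symbol and 1 by synonym in the count table with 4 unmatched, and 422 and 9 in the normalized table with 5 unmatched. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists), again with an estimated correlation, and with fry. Some genes stand in several lists, so the lists are not independent.

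Named genes followed a rule: Bcl11b and Foxp3; the 8 largest rises and falls among called genes with a mean of at least 5 CPM and no overlap between groups (4 each for KO EAE against WT), without predicted, antigen receptor and sex-linked genes; up to 4 called members with the smallest p of each list (all where 5 or fewer were called, the smallest p where none was); and the 2 most abundant members of lists of other cell types. Some genes taken by the rule are not reported here, though counts of genes include them. Mki67, Ifit3, Xist, Gpr83, Cd160 and Slc25a33 fall outside the rule and were chosen after their values were seen.

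The alternatives set beforehand were DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0 in place of edgeR, only the libraries of the groups compared, the replicate number as a block, and each library left out in turn. Added after the data were seen were the recovered reads with edgeR and with DESeq2, a fit without ribosomal protein and predicted Gm genes, a block with the WT numbers crossed, and the list tests of KO EAE against WT under the alternatives. Also added was a split of each library's reads at random in 2 parts, to see how far counting error alone lowers the correlation of replicate differences between the tables. Groups of 2 are too small for a test of outlying samples or of other splits of the samples.

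The edgeR test was tested on 1 simulated data set per comparison, drawn from the means, dispersions and library sizes over all 6 libraries. In each, 50 genes were changed at each true fold and the cell cycle list was raised 1.5-fold. For KO against WT (14256 genes run) it recovered 96% of genes at a true fold of 4, 60% at 2, 48% at 0.5 and 88% at 0.25, and 6.33% of calls were false. For KO EAE against KO (14250 genes) these were 90%, 70%, 50% and 78%, with 12.9% false, and for KO EAE against WT (14257 genes) 74%, 60%, 60% and 86%, with 10.7% false, all above the nominal rate. Camera called the raised list each time. It also called 1 other list for KO EAE against KO and 0 in the other comparisons. Genes were drawn independently of each other, so correlation within lists was not imitated. In the data that correlation was estimated at 0.917 for the cell cycle list in KO against WT. These simulations therefore do not check camera on correlated lists. Shared WT controls were imitated by 40 simulations of unchanged groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.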

Results

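Gene expression was measured by RNA sequencing in 6 libraries of mouse regulatory T cells, the Foxp3-expressing T cells that restrain immune responses. The cells had been sorted from spleen and peripheral lymph nodes. The libraries formed 3 groups of 2: wild type (WT) at steady state, Bcl11b knockout (KO) at steady state, and KO with EAE, which in this field stands for experimental autoimmune encephalomyelitis, a mouse model of multiple sclerosis. Bcl11b is a zinc finger transcription factor that T cells need to form and to keep their identity. The series asks how its removal changes the transcriptome of regulatory T cells. The deposited count table held 16512337 and 16501787 reads in WT replicates 1 and 2, 16904312 and 14663542 in the KO replicates, and 15704030 and 15525373 in the KO EAE replicates. A limit of 3 reads corresponded to 0.177 to 0.205 counts-per-million (CPM), for counting error alone. No label says that replicates came from separate animals or sorts, so the p-values below measure only the spread between these samples, which may be technical. No WT EAE library was analysed here, so the effect of genotype in EAE was not testable.

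Bcl11b (chromosome 12, 107910403 to 108003602, mm10) was read in every library. WT replicates 1 and 2 had 420 and 425 CPM, KO replicates 371 and 370 CPM, and KO EAE replicates 404 and 278 CPM. The log2 change from WT to KO was -0.19 ± 0.17 (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.527), so no loss of the whole-gene count was called. A whole-gene count does not isolate the floxed part of the gene, which the labels do not name, and it therefore checks the genotype labels little. The strain label of the KO libraries names 1 floxed and 1 wild-type Bcl11b allele with the Foxp3 Cre driver, while their genotype label says KO; the WT strain label names 2 floxed alleles and no Cre. In the authors' normalized table, which holds other values for WT and KO libraries, the reads recovered gave -0.87 ± 0.14 (edgeR, adjusted p = 0.0987), and the authors' deposited table of fold changes lists Bcl11b at -0.80 with an adjusted p of 7.9e-08. Foxp3 (chromosome X, 7573644 to 7595245), the lineage-defining factor of regulatory T cells, averaged 208 ± 3.10 CPM in WT (SD, n = 2), 160 ± 6.62 in KO and 156 ± 9.76 in KO EAE. It fell by 0.38 on the log2 scale from WT to KO (edgeR, adjusted p = 0.0254), lower in both KO libraries. Leaving out any 1 of the 4 libraries ended that call (adjusted p 0.106 to 0.185), and the normalized table gave -0.07 (adjusted p = 0.891).

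**Figure D1:**
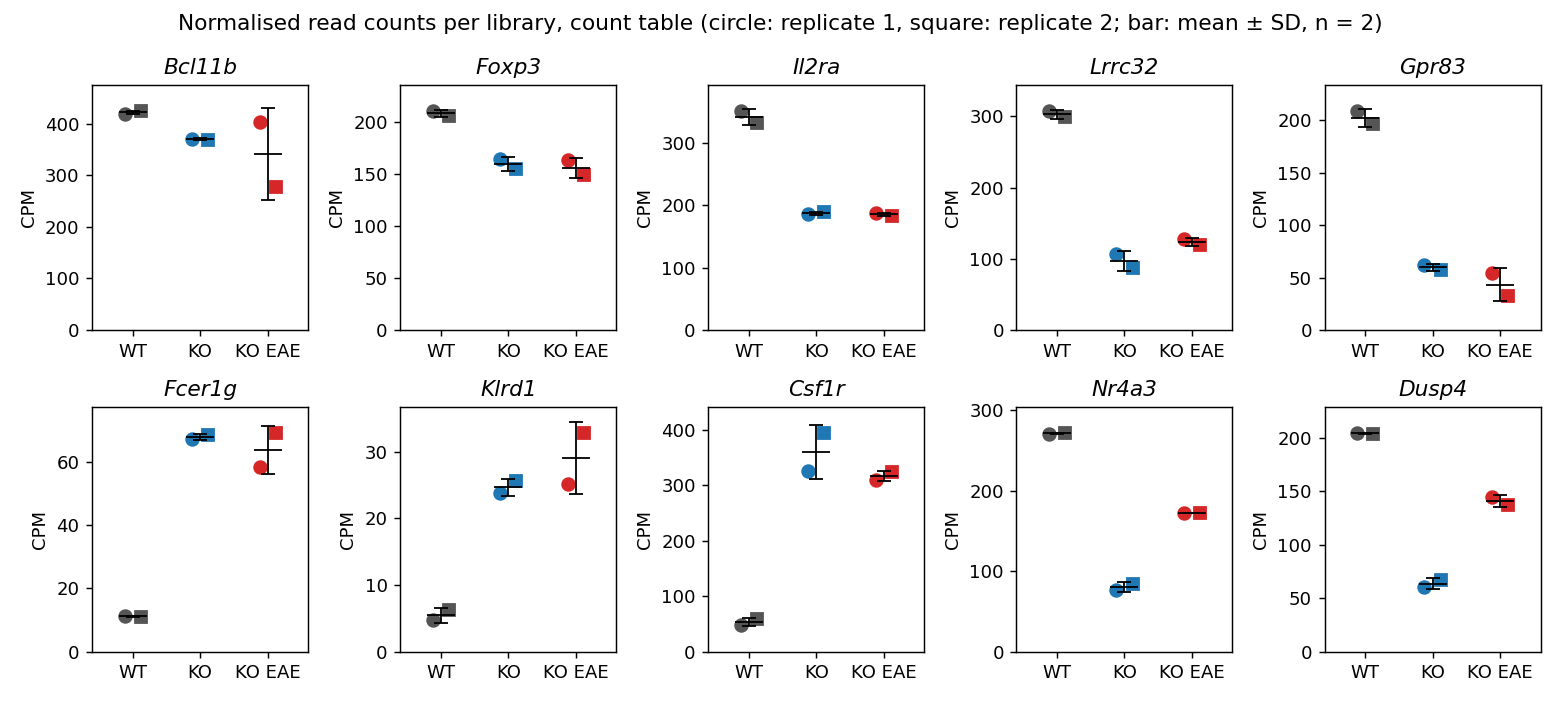
Expression of 10 genes in the 6 libraries of the count table, in CPM on linear axes from 0, with circles for replicate 1, squares for replicate 2 and bars for the mean ± SD of n = 2. Lrrc32, Gpr83 and Il2ra sit lower in both KO groups than in WT, Fcer1g, Klrd1 and Csf1r higher, while Nr4a3 and Dusp4 are lowest in steady-state KO.

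Genes of the regulatory T cell signature fell in KO cells at steady state. Of 27 measured members of the fixed list, 17 fell and 1 rose (21 and 1 adjusted over the list alone), with a median log2 change of -0.58. Lrrc32 (chromosome 7, 98489283 to 98502181), which docks latent TGF-beta on the cell surface, fell by 1.65 on the log2 scale, from 303 ± 6.15 to 96.6 ± 13.6 CPM (SD, n = 2). Il2ra (chromosome 2, 11642807 to 11693193), the high-affinity chain of the interleukin-2 receptor, went from 342 ± 13.1 to 188 ± 2.43 CPM, a log2 change of -0.87 ± 0.07 (adjusted p = 0.000829). Socs2 and Cish, feedback inhibitors of cytokine signalling that STAT5 induces, changed by -1.29 ± 0.08 and -0.74 ± 0.06. The list of interleukin-2, STAT5 and related cytokine signals shares such genes, and 9 of its 24 members fell while Il2 itself rose (12 and 1 adjusted over the list alone). Il2 went from 0.563 and 0.674 CPM to 5.51 and 6.14 CPM. By camera, the signature list was lower than other genes (adjusted p = 8.09e-11) and so was the cytokine list (adjusted p = 0.000471). With an estimated correlation these became adjusted p = 0.255 and adjusted p = 0.639. In the same KO libraries myeloid markers had a median log2 change of 3.26 and T cell identity genes of -0.07. Both KO libraries lay below both WT libraries for each falling gene named here, and those calls held with any 1 library left out.

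Genes of natural killer (NK) cells and of cytotoxic T cells were higher in the KO libraries. Of 21 measured members of that list, 15 rose and none fell (18 and 0 adjusted over the list alone), with a median log2 change of 1.86. Fcer1g (chromosome 1, 171229572 to 171234365), a signalling adaptor of Fc and NK receptors, rose from 11.1 ± 0.0364 to 67.8 ± 0.963 CPM (SD, n = 2; log2 change 2.61 ± 0.11, adjusted p = 7.72e-05). The related adaptor Tyrobp changed by 2.34 ± 0.12. Klrd1 (chromosome 6, 129591782 to 129598775), the CD94 chain of NK receptors, rose from 5.47 ± 1.10 to 24.7 ± 1.28 CPM, and Klrb1c, which encodes the NK1.1 antigen, from 9.95 and 10.5 to 47.6 and 34.3 CPM. Camera placed the list above other genes (adjusted p = 1.01e-11; adjusted p = 0.324 with an estimated correlation). Macrophage and dendritic cell markers, described next, rose in the same 2 libraries with a median log2 change of 3.26.

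Markers of macrophages and dendritic cells, and genes of MHC class II presentation, also rose in KO libraries. Of 20 measured myeloid markers 11 rose and none fell (15 and 0 adjusted over the list alone). Adgre1, which encodes F4/80, went from 20.6 ± 2.59 to 238 ± 35.0 CPM (SD, n = 2), and Csf1r (chromosome 18, 61100598 to 61132149), the receptor for macrophage growth factor, from 53.4 ± 7.51 to 360 ± 49.0 CPM. The integrin chain gene Itgax changed by 4.24 ± 0.21 on the log2 scale (adjusted p = 0.000106) and the Fc receptor gene Fcgr3 by 3.57 ± 0.18 (adjusted p = 0.000117). Of 10 MHC class II genes 8 rose and none fell (8 and 1 adjusted over the list alone), among them H2-DMb1 at 3.62 ± 0.21 and H2-Aa at 2.36 ± 0.14. Camera gave adjusted p = 1.51e-22 for the myeloid and 7.1e-10 for the MHC class II list; both had adjusted p = 0.324 with an estimated correlation. Of 4 measured erythroid markers 3 rose (4 adjusted over the list alone; camera adjusted p = 0.0131, adjusted p = 0.702 with an estimated correlation), including Alas2 at 2.74 ± 0.47 and Slc4a1 at 3.89 ± 0.67. The calls of Alas2 and Slc4a1 held in 1 of 4 fits that each left out a library (highest adjusted p 0.0902 and 0.0841).

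Markers of further cell types showed higher medians without a list call. The B cell list had a median of 2.05 over 13 genes with 1 called, Cd22 at 2.05 ± 0.35 (camera adjusted p = 0.104). Cd79b, the most abundant with Cd22, changed by 0.17 (adjusted p = 0.699). All 13 B cell markers were higher in KO replicate 2 than in KO replicate 1 (median log2 ratio 1.33). Of 6 plasma cell markers 1 rose, Sdc1 (list median 0.90, adjusted p = 0.348). Of 11 stromal and endothelial markers 2 rose, Igfbp7 and Pdgfrb (list median 1.10, adjusted p = 0.326). Of 4 CD8 lineage genes Crtam rose by 1.46 ± 0.32 (list adjusted p = 0.537), while Cd8b1 stayed at 17.9 and 21.2 CPM in KO against 25.8 and 24.4 in WT (adjusted p = 0.18). Leaving out any 1 of the 4 libraries ended the calls of Cd22, Sdc1, Pdgfrb and Crtam (highest adjusted p 0.0942, 0.235, 0.174 and 0.17), and 3 of the 4 fits ended that of Igfbp7 (highest 0.143). Without KO replicate 1 the B cell, plasma cell and stromal lists were called higher (adjusted p = 9.77e-06, 0.0181 and 0.0368).

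Among helper T cell programmes, genes of type 1 helper (Th1) cells and of follicular T cells rose, while the Th2 and Th17 lists were not called. In the Th1 list 7 of 15 measured genes rose and 1 fell (13 and 1 adjusted over the list alone). Tbx21, the master regulator of Th1 cells, rose from 14.1 and 14.9 CPM to 83.4 and 63.3 CPM, and Eomes, Ccl5 and Ifng changed by 1.34, 0.83 and 0.98 on the log2 scale. Of 12 follicular genes 4 rose (7 adjusted over the list alone), and those were Cebpa, Pdcd1, Sostdc1 and the cytokine Il21, which went from 1.94 and 1.72 to 43.6 and 25.1 CPM. Camera adjusted p was 0.00275 for Th1 and 0.00667 for follicular genes; with an estimated correlation these were adjusted p = 0.702 and adjusted p = 0.521. Of 12 Th2 genes 3 rose and 3 fell (median -0.12, mean 0.58, adjusted p = 0.358), with Pparg at 4.20 ± 0.27 and Ccr3 at 3.48 ± 0.23 against Il10 at -1.67 ± 0.22 and Areg at -2.67 ± 0.37. Of 15 Th17 genes 3 rose, Il21, Tmem176a and Tmem176b (median 1.37, adjusted p = 0.0886; 0.00042 without KO replicate 1 and 0.012 without WT replicate 2). Myeloid markers, with a median of 3.26, and NK and cytotoxic genes, with a median of 1.86, rose in the same KO libraries. Which cells carried the higher Th1 and follicular genes cannot be told from these libraries. The calls of Ccl5 and Tmem176b were lost without any 1 of the 4 libraries (highest adjusted p 0.102 and 0.147), and those of Eomes, Ifng, Pdcd1, Tmem176a and Il10 in 2 or 3 of those 4 fits (highest 0.0718, 0.102, 0.172, 0.13 and 0.0613). Pdcd1, Il10 and the medians of the follicular, Th2 and Th17 lists had the opposite sign in the normalized table (-0.41, 0.52, -0.12, 0.29 and -0.38), where none of these 3 lists was called (adjusted p = 0.237, 0.565 and 0.557). Before TMM scaling Tbx21 had 29.2 and 45.4 CPM in WT and 47.2 and 39.1 in KO there. Il21 had 31.9 and 17.6 CPM in WT and 30.3 and 25.7 in KO. The authors' deposited table lists Tbx21 at 0.13, Il21 at 0.09, Cebpa at 0.01 and Pparg at 0.04 (DESeq2, adjusted p = 0.86, 0.926, 0.989 and 0.869). It lists Ifng at 0.92 (adjusted p = 0.000982). For genes that edgeR called in both tables, the authors' log2 changes lay nearer 0 than edgeR gave on recovered reads (Klrd1 1.52 against 3.31). Their sizes are therefore not comparable with the edgeR values above. Pparg had 0 and 66 recovered reads in WT and 148 and 203 in KO.

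Immediate-early genes that antigen receptor signals induce were lower in the KO libraries of the count table. Of 20 measured members 4 fell and none rose (7 and 0 adjusted over the list alone), with a median log2 change of -0.32. Nr4a3 (chromosome 4, 48045153 to 48086447), an orphan nuclear receptor used as a reporter of receptor signalling, fell from 271 ± 0.900 to 80.4 ± 5.97 CPM (SD, n = 2; -1.75 ± 0.08, adjusted p = 8.17e-05). Its relatives Nr4a2 and Nr4a1 changed by -1.77 ± 0.22 and -0.68 ± 0.13, and Nfkbid by -0.57 ± 0.14. Camera gave adjusted p = 0.000103, and adjusted p = 0.702 with an estimated correlation. Leaving out any 1 library ended the call of Nfkbid (highest adjusted p 0.259), and 3 of 4 such fits ended that of Nr4a1 (highest 0.121). The KO libraries stood apart on this list, with 17 of the 20 genes higher in replicate 2 than in replicate 1 (median log2 ratio 0.37). The list median was -0.14 without KO replicate 1 and -0.50 without KO replicate 2, and the list call held in both fits. Myeloid markers had a median log2 change of 3.26 in the same KO libraries. In the normalized table the direction was lost as well as the call (median 0.01, mean 0.12, adjusted p = 0.873).

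Of 25 genes of effector regulatory T cells 5 rose and 4 fell (camera adjusted p = 0.497); Irf4 and Nfil3, regulators of effector differentiation, changed by -0.69 ± 0.07 and -1.47 ± 0.19, Areg by -2.67 ± 0.37, and Id2 by 0.74 ± 0.10. Sterol synthesis genes fell modestly, while myeloid markers had a median log2 change of 3.26 in the same KO libraries. Of 20 sterol genes 5 fell (7 adjusted over the list alone), among them Mvd at -0.50 ± 0.10 and Sqle, which encodes squalene epoxidase, at -0.40 ± 0.10. The sterol list median was -0.21, against -0.04 in the normalized table (camera adjusted p = 0.509). That list had camera adjusted p = 0.0339 (adjusted p = 0.419 with an estimated correlation, 0.0501 without WT replicate 2), and Mvd and Sqle lost their calls without any 1 of the 4 libraries (highest adjusted p 0.196 and 0.261). The glucose transporters Slc2a1 and Slc2a3 fell by 0.75 and 0.72 on the log2 scale, the only members called among 17 glycolysis genes (list adjusted p = 0.175). Of 28 homing receptors 4 rose and 3 fell, with Cxcr6 at 2.06 ± 0.18 and the integrin chain Itgb8 at -1.64 ± 0.18 (list median 0.03, camera direction down, adjusted p = 0.859). Of 16 genes of naive and central cells 1 rose and 1 fell, with Dapl1 at 0.74 ± 0.16 (list adjusted p = 0.348). Of 20 T cell identity genes Themis, a regulator of receptor signalling, rose by 0.75 ± 0.08 (list median -0.07, adjusted p = 0.348). In 18 survival genes Bcl2a1d and Bcl2a1b rose and Bcl2l1 and Fas fell (list adjusted p = 0.209); Bcl2a1b and Bcl2a1d are near-identical copies and their split is uncertain. The calls of Dapl1, Bcl2l1 and Fas were lost without any 1 of the 4 libraries (highest adjusted p 0.2, 0.262 and 0.257) and that of Bcl2a1b in 3 of those fits (highest 0.116). In the normalized table Nfil3, Mvd, Sqle, Bcl2l1 and Fas had the opposite sign (0.07, 0.39, 0.03, 0.03 and 0.00205), and so did the medians of the survival list (0.09, against -0.26), the naive and central list (0.15, against -0.06), the effector list (0.0472, against -0.0536) and the homing list (-0.058, against 0.0253). None of 30 cell cycle, 24 type I interferon response or 32 oxidative phosphorylation genes was called by edgeR (list adjusted p = 0.236, 0.0759 and 0.348), where the smallest adjusted p among single members were those of E2f1, Isg20 and Sdhc at 0.176, 0.161 and 0.216. The unadjusted p was under 0.05 for 4128 genes in all, and DESeq2 called 2425. Without WT replicate 2 the interferon list was called lower (median -1.10, adjusted p = 1.54e-14), without KO replicate 1 both the interferon and the cell cycle list were called (0.0435 and 0.0181), and without KO replicate 2 the survival list was called lower (0.0151).

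**Figure D2:**
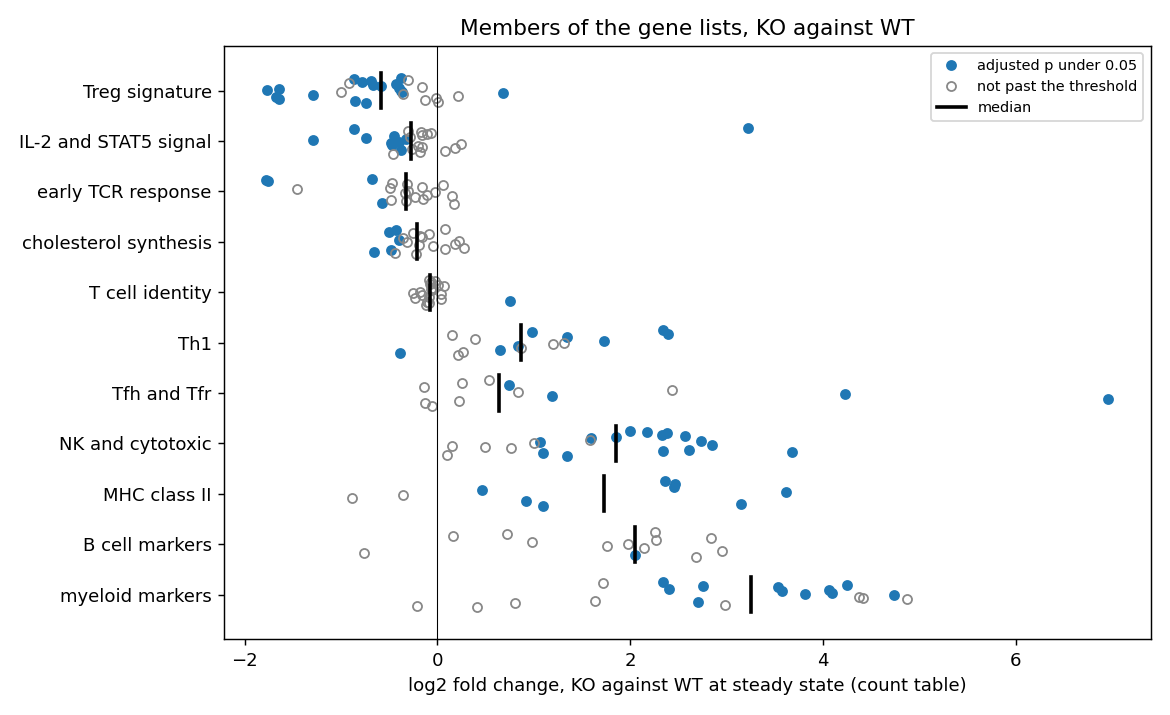
Log2 change of each measured member of 11 fixed gene lists, KO against WT at steady state in the count table, with filled points for genes at an adjusted p under 0.05 and a black line at the list median. The medians run from -0.58 in the regulatory T cell signature to 3.26 in the myeloid markers.

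Over all 14548 genes tested, 1369 rose and 504 fell from WT to KO, 1060 and 169 of them by more than 2-fold. The largest rises by the fixed rule were Sostdc1 at 6.96 ± 1.08, Cox6a2 at 5.57 ± 0.43, Lilra6 at 5.43 ± 1.04, B3galnt1 at 5.38 ± 0.31, Fgf1 at 5.29 ± 0.38, Clec4b1 at 5.21 ± 0.47, Kcnk13 at 5.16 ± 0.48 and the amino acid transporter Slc7a8 at 5.14 ± 0.27. All 8 had WT values of 0.122 to 3.49 CPM. The largest falls were Supt4b (-5.56 ± 0.99) and Rps16 (-3.65 ± 0.66), both uncertain because near-identical copies can share their reads, then Ntn4 (-3.22 ± 0.52), Myh7b (-3.02 ± 0.43), Syde2 (-2.90 ± 0.29), the growth factor Areg, Drc1 (-2.57 ± 0.30) and Amn (-2.56 ± 0.47). Of the 1369 genes that rose, 334 averaged under 1 CPM in WT. With 1 library left out, 846 (without KO replicate 1), 847 (without WT replicate 1), 896 (without KO replicate 2) and 917 (without WT replicate 2) genes were called, and 42 of the 79 named genes called in this comparison kept their call in all 4 fits. Sostdc1, Lilra6, Supt4b, Rps16, Ntn4, Myh7b, Areg and Amn did not (highest adjusted p 0.0568 to 0.157). Fgf1, Rps16, Ntn4, Syde2 and Amn had the opposite sign in the normalized table (-0.01, 0.19, 1.43, 6.92 and 0.11). Few reads set the values of Syde2 and Amn, whose mean signal in the authors' comparison was 7.34 and 5.27. Sostdc1 had 21.2 and 29.8 CPM in WT and 38.5 and 25.4 in KO in the normalized table, before TMM scaling. The authors' deposited table lists it at 0.20 (DESeq2, adjusted p = 0.777), and Slc7a8 at 0.98 (adjusted p = 0.000795). For Cox6a2, Lilra6, B3galnt1, Fgf1, Clec4b1 and Kcnk13 it lists log2 changes of 0.00506 to 0.306 and no adjusted p. The mean signal it gives for these genes is 5.93 to 40.4. Its log2 changes are not comparable in size with those of edgeR, so these values do not show that the genes were unchanged.

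The authors' normalized table gave a smaller set of changes for WT and KO. Whole reads were recovered from it (16884434 and 19410133 in WT, 25335011 and 24065561 in KO), and edgeR called 12 of 12253 genes there, 8 higher and 4 lower, against 372 by DESeq2 and 349 in the authors' deposited table of fold changes. At an unadjusted p under 0.05 edgeR had 1533. In this paragraph 7 genes called by edgeR in both tables, all with 1 direction, are named after their values were seen. Klrd1 changed by 3.31 ± 0.36 in the normalized table, Fcer1g by 3.30 ± 0.20, the NK and T cell receptor Cd160 by 2.17 ± 0.21, Dapl1 by 1.97 ± 0.22 and the mitochondrial pyrimidine carrier Slc25a33 by 1.97 ± 0.19. Lrrc32 changed by -1.56 ± 0.18 and Gpr83, a G protein-coupled receptor enriched on regulatory T cells, by -1.37 ± 0.15. Fcer1g had an adjusted p of 0.00689 and the other 6 of 0.0494. Independent lists of these sizes would share 0.748 higher and 0.147 lower genes, where 5 and 2 were shared. Camera called 8 lists there, with the NK list (median 1.67, adjusted p = 6.15e-22), the regulatory T cell signature (-0.51, 3.31e-20), myeloid markers (1.10, 1.26e-09), MHC class II (0.61, 0.000194), cytokine signals (-0.21, 0.000219) and Th1 (0.25, 0.0223) in the direction of the count table. Their adjusted p with an estimated correlation was 0.251 to 0.551. Of the other lists, oxidative phosphorylation was higher (0.31, adjusted p = 3.55e-08; -0.04 in the count table) and the interferon list lower (-0.09, adjusted p = 0.0223). With an estimated correlation these became adjusted p = 0.51 and adjusted p = 0.736. The early receptor response, follicular, sterol and erythroid lists, called in the count table, were not called there (adjusted p = 0.873, 0.237, 0.509 and 0.237). In all, 9 list medians had opposite signs in the 2 tables.

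**Figure D3:**
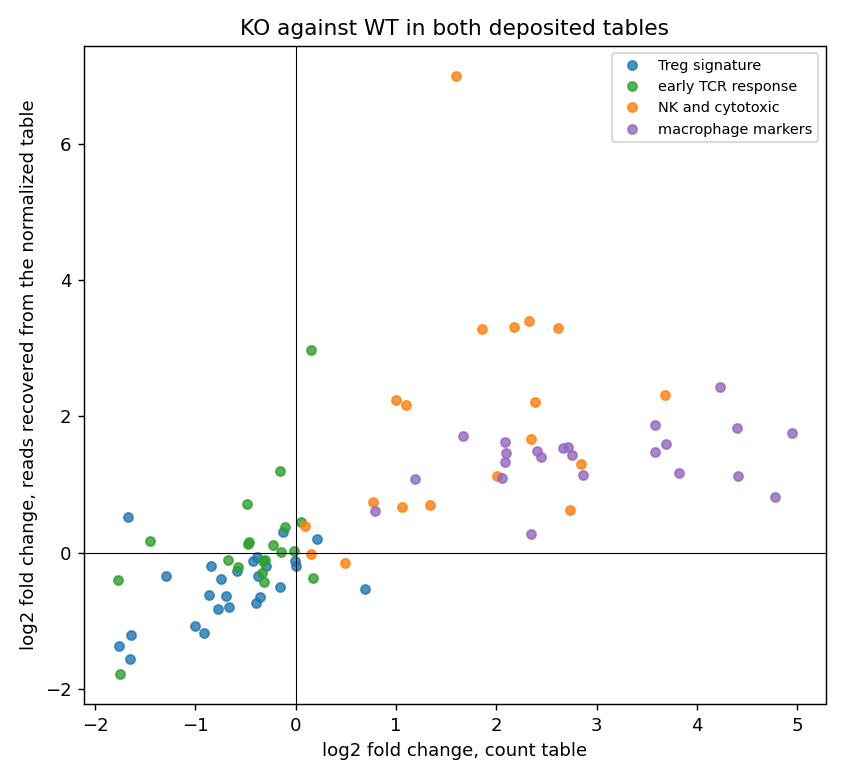
Log2 change from WT to KO in the count table (x axis) and from reads recovered from the normalized table (y axis) for genes of the regulatory T cell signature, early receptor response, NK and macrophage lists that carry 1 name in both tables. Fcer1g lies at 2.61 and 3.30 and Lrrc32 at -1.65 and -1.56.

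The 2 tables did not hold the same measurements under the same library names. Across 8529 gene names in both tables with a mean log2(CPM + 1) above 4, which are not independent replicates, same-named libraries correlated with Spearman coefficients of 0.707 to 0.756, while WT and KO replicates within a table reached 0.973 to 0.985. Log2 changes from WT to KO correlated at 0.287 across the 11790 genes tested in both. Genes at 0.5 to 5 CPM in the normalized table had 1.80 to 2.68 times as much in the count table, and genes above 500 CPM had 0.292 to 0.330 times as much. Xist, the X-inactivation transcript of female cells, had 469 and 1.33 CPM (22 reads) in WT replicates 1 and 2 of the count table and 621, 447, 507 and 345 CPM in the KO and KO EAE libraries, against 106 and 75.0 CPM in WT and 67.6 and 88.8 in KO in the normalized table.

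Comparing KO cells in EAE with KO cells at steady state, 2 genes changed and both rose. Nr4a3 went from 80.4 ± 5.97 to 173 ± 0.148 CPM (SD, n = 2; log2 change 1.10 ± 0.08), against 271 ± 0.900 in WT. Dusp4 (chromosome 8, 34807297 to 34819894), a phosphatase that dampens MAP kinase signals, went from 63.6 ± 4.89 to 141 ± 5.54 CPM (1.15 ± 0.08), against 204 ± 0.415 in WT. Both KO EAE libraries were higher than both KO libraries, with an adjusted p of 0.0455 for each. DESeq2 called 167 genes, 57 higher and 110 lower, and edgeR had 1378 at an unadjusted p under 0.05. Without KO replicate 1 or 2 edgeR called 0 (604 and 1271 at an unadjusted p under 0.05), without KO EAE replicate 1 it called 313, and without KO EAE replicate 2 it called 8; with the replicate number as a block it called 0 (1360 unadjusted).

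As lists, early receptor response genes were higher in KO EAE than in KO by camera (median 0.23 over 20 genes with 1 called, adjusted p = 6.74e-09), and they kept that call without each of the 4 libraries. Their median was 0.04 without KO replicate 1 and 0.42 without KO replicate 2, and 17 of the 20 were higher in KO replicate 2 than in KO replicate 1. Camera also placed 5 further lists higher: cell cycle (median 0.65, adjusted p = 1.89e-11), interferon response (0.61, 1.3e-05), effector regulatory T cells (0.13, 0.000296), glycolysis (0.11, 0.00183) and cytokine signals (0.08, 0.0137). With an estimated correlation all 6 had adjusted p between 0.846 and 0.875, and by fry between 0.358 and 0.842. Adjusted over the list alone, 2 early response, 2 effector, 2 cytokine and 1 glycolysis gene rose, and no cell cycle or interferon gene did. Mki67, the proliferation marker, had 210 and 539 CPM in KO EAE replicates 1 and 2 against 198 and 220 in KO, and Ifit3, induced by interferon, had 118 and 374 against 104 and 96.8. Without KO EAE replicate 2 the cell cycle median was 0.01 (adjusted p = 0.585), the interferon median 0.21 (0.123) and the effector median -0.03 (0.304). Without KO EAE replicate 1 cytokine signals had adjusted p = 0.743 and glycolysis 0.051, and without KO replicate 1 cytokine signals had 0.0818. Of the other 19 lists none was called (adjusted p 0.0616 to 0.786), including the regulatory T cell signature (median 0.05), NK genes (0.02, mean -0.23) and myeloid markers (-0.22). With 1 library left out, 14 of these 19 were called in at least 1 fit, among them NK genes (-0.27, adjusted p = 3.72e-05) and myeloid markers (-0.48, adjusted p = 8.61e-05), both lower without KO EAE replicate 2.

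KO cells in EAE differed from WT cells at steady state in genotype and disease together, so only their joint difference is reported. The regulatory T cell signature was again lower, with 15 of 27 genes down and none up (19 and 1 adjusted over the list alone). Lrrc32 stood at 123 ± 5.64 CPM (SD, n = 2; log2 change -1.30 ± 0.11), Il2ra at 186 ± 2.53 CPM (-0.88 ± 0.07), Socs2 changed by -1.12 ± 0.08 and Swap70 by -1.14 ± 0.11. Of 21 NK and cytotoxic genes 14 rose (15 adjusted over the list alone), with Fcer1g at 63.7 ± 7.65 and Klrd1 at 29.0 ± 5.37 CPM, alongside 10 of 20 myeloid markers (16 adjusted over the list alone) such as Csf1r at 317 ± 9.28 CPM and 7 of 10 MHC class II genes (8 adjusted over the list alone). Of 15 Th17 genes 4 rose (7 adjusted over the list alone), among them the cytokine gene Il17a, with 12.3 and 20.2 CPM against 1.31 and 2.08 in WT (3.25 ± 0.56, adjusted p = 0.0183; up to 0.12 with 1 library left out). Of 30 cell cycle genes E2f1 rose (26 adjusted over the list alone), with an adjusted p of up to 0.212 when 1 library was left out. The KO EAE libraries stood apart on this list: all 30 genes were higher in replicate 2 than in replicate 1 (median log2 ratio 1.13), and Mki67 had 210 CPM in replicate 1 and 539 CPM in replicate 2, against 159 and 134 in WT and 198 and 220 in KO. The list median was 1.23 (camera adjusted p = 3.21e-06, and 0.786 with an estimated correlation). It was 0.50 without KO EAE replicate 2 and 1.68 without KO EAE replicate 1.

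In that joint comparison 1362 genes changed, 1078 higher and 284 lower, 871 and 102 of them by more than 2-fold. Sostdc1, Lilra6, Clec4b1 and the collagenase gene Mmp13 led the rises (5.68, 5.23, 5.10 and 5.06), and Ntn4, Stra6, Khdc1a and Rps16 the falls (-3.91, -3.26, -3.26 and -3.24). Without 1 library 603 (WT replicate 1), 671 (WT replicate 2), 3762 (KO EAE replicate 1) and 1102 (KO EAE replicate 2) genes were called. Of these 8 genes Clec4b1 and Ntn4 kept their call in all 4 fits, and the highest adjusted p of the others was 0.0709 to 0.139. Camera called 10 lists: signature (3.27e-11), cytokine signals (0.00494), NK (6.74e-12), myeloid (2.02e-22), MHC class II (2.3e-10), Th1 (5.35e-05), Th17 (0.00253), follicular (0.00183), erythroid (0.00313) and cell cycle (3.21e-06). Their adjusted p with an estimated correlation was 0.243 to 0.786. Without KO EAE replicate 2 cytokine signals were not called (adjusted p = 0.0597). The interferon list, not called (median 0.04, camera direction down, adjusted p = 0.853), was called higher without WT replicate 1 (1.01, adjusted p = 4.16e-08) and lower without WT replicate 2 (-0.39, adjusted p = 9.19e-05).

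Many differences from WT were called in both KO groups. Of the genes that differed, 996 were higher and 203 lower in both comparisons, and 0 were called in opposite directions. Independent lists of these sizes would share 101 and 9.84 genes. In 40 simulations of unchanged groups, with simulated WT libraries serving both comparisons, at most 2 genes were shared. With no difference simulated few calls arise, so that count is no reference for the overlap seen. All libraries were drawn from 1 mean per gene, so an offset of the real WT libraries was not imitated. The log2 changes had a covariance of 0.871 across genes against 0.0686 in the simulations, and a correlation of 0.891 against 0.498. The 2 WT libraries serve both comparisons and cannot be split, so part of the excess may come from them.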

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

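The recovered reads of the normalized table, with edgeR or DESeq2, the fit without ribosomal protein and predicted genes, the crossed block and the list tests of KO EAE against WT under alternatives were chosen after seeing the data; the others were set before. Unless a cause is given, the cause was not tested.

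Of 2042 values of named genes over all alternatives, 1606 kept direction and side of the threshold, 370 kept direction but lost the call, 19 gained it and 47 changed sign, 24 of these with no call in either fit. Of 800 list medians these were 646, 50, 52, 52 and 45. Fitting only the libraries compared gave 3121 changed and 1100 lower genes for KO against WT, 0 changed and 0 higher for KO EAE against KO (940 at an unadjusted p under 0.05), and for KO EAE against WT 782 changed, 649 higher and 133 lower, with 761 shared between both comparisons against WT. DESeq2 gave 167 changed, 57 higher and 110 lower for KO EAE against KO, and 2227 changed and 628 lower for KO EAE against WT. No filter gave 1 lower gene for KO EAE against KO. Recovered reads gave 12 changed, 8 higher and 4 lower for KO against WT by edgeR, and 372, 195 and 177 by DESeq2, which kept 152 of the 1873 calls. Higher genes were 73.1% of the calls for KO against WT and 79.1% for KO EAE against WT.

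Leaving out 1 library, where the lone library is assumed to vary like the other groups, gave 846 to 917 changed genes for KO against WT (721 to 769 higher, 100 to 175 lower), 0 to 313 for KO EAE against KO (0 to 207 higher, 0 to 106 lower) and 603 to 3762 for KO EAE against WT (542 to 2105 higher, 61 to 1657 lower). The highest values of the last 2 came without KO EAE replicate 1. The shared genes ran from 577 to 2151, the lists called from 10 to 16 for KO against WT from 5 to 11 for KO EAE against KO and from 9 to 12 for KO EAE against WT. Of the named genes, 42 of 79 called for KO against WT kept the call in all 4 fits, and 27 of 65 for KO EAE against WT.

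Of the lists, 10 were called for KO against WT, 0 with an estimated correlation and 7 by fry; 6 were called for KO EAE against KO, 0 with an estimated correlation and 0 by fry; and 10 for KO EAE against WT, 0 with an estimated correlation and 6 by fry. Whether replicate numbers pair the libraries cannot be settled with 2 libraries per group. Deviations of same-numbered libraries correlated across genes at 0.0593 for WT and KO, -0.211 for WT and KO EAE and 0.178 for KO and KO EAE. As a block the replicate numbers gave 0 changed and 0 higher genes and 10 lists for KO EAE against KO. In the comparisons with WT the block gave 1668 and 1301 genes, and 12 lists for KO against WT. The replicate block with the WT numbers crossed called 1388 genes for KO EAE against WT.

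These log2 changes from WT to KO, called in the count table, turned with recovered reads (edgeR, then DESeq2): Rps16 0.19 and 0.19, Ntn4 1.43 and 1.42, Syde2 6.92 and 6.09, Nfil3 0.0687 and 0.0599, Il10 0.52 and 0.52, Pdcd1 -0.41 and -0.42, Ccr8 0.0472 and 0.044, Bcl2l1 0.0251 and 0.0186, Mvd 0.39 and 0.38, Sqle 0.0335 and 0.0263, and with edgeR alone Fgf1 -0.0105, Amn 0.11 and Fas 0.00205. Few reads set the values of Syde2 and Amn, whose mean signal in the authors' comparison was 7.34 and 5.27. With recovered reads 9 list medians changed sign: follicular genes (-0.12), oxidative phosphorylation (0.31) and early receptor response (0.0136), each called in 1 of the tables, and Th17 (-0.38), Th2 (0.29), naive and central (0.15), survival (0.09), effector (0.0472) and homing genes (-0.058), called in neither. In KO EAE against KO, 3 called medians changed sign without KO EAE replicate 2: Th1 (-0.18, against 0.24 without KO EAE replicate 1), effector (-0.0271) and NK genes (-0.27). In KO EAE against WT the interferon list was called higher without WT replicate 1 (1.01) and lower without WT replicate 2 (-0.39). Genes under 3 reads (0.177 to 0.205 CPM in the count table) are below what this depth can show, and 334 of the rises start from under 1 CPM in WT, where few reads set the fold.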

Other observations

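All tests of explanations below were chosen only after the results were seen.

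Some gene groups differed between the 2 replicates of a group. All 24 measured interferon response genes were lower in WT replicate 2 than in replicate 1 (median log2 ratio -1.48), and Ifit3 had 43.6 against 407 CPM. In KO EAE 23 of the 24 were higher in replicate 2 (0.72). All 30 cell cycle genes were higher in KO EAE replicate 2 than in replicate 1 (1.13). All 13 B cell markers were higher in replicate 2 than in replicate 1 in KO (1.33) and in KO EAE (1.22). WT replicate 2 had 22 Xist reads, and no Y chromosome gene had a read in any library of either table (45 genes in the count table and 43 in the normalized table). Whether Y-linked reads would have been counted is unknown, so these zeros are no check of that library.

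Macrophage and other non-T-cell markers were higher in the KO libraries. A list of 24 macrophage genes, written after the largest changes were seen and with 4 of them also in the fixed myeloid list, had a median log2 change of 2.73 with 24 called; before TMM scaling Csf1r had 339 and 395 CPM in KO against 46.6 and 58.1 in WT, and Vcam1 301 and 343 against 48.4 and 65.4, while Cd4 had 290 and 315 against 282 and 285. The way reads were counted in that table is argued against, since all 24 were also higher in the normalized table, with a median of 1.47 (SD over genes 0.44). RNA from macrophages and other cells, which a sort for regulatory T cells is meant to remove, may be the source: the lowest median over 5 lists of other cell types was 0.90, although in the normalized table the B cell and stromal medians were 0.03 and 0.12. Expression of macrophage genes by KO regulatory T cells cannot be told apart from this, because the T cell identity median of -0.0731 leaves room for both.

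Of 21 genes of the NK list 15 rose in KO and 14 in KO EAE, while genes restricted to NK cells had a median log2 change of -0.14 from WT to KO EAE (SD 1.31, 4 of 8 higher, 1 called lower and none higher). Counting is argued against, with 89.5% of the NK list higher in KO in the normalized table, while RNA from NK cells in the KO sorts remains a candidate explanation: genes restricted to NK cells had a median log2 change of 1.36 (SD 1.32, 7 of 8 higher), near the 1.76 of genes that T cells can also express, although only 2 of the 8 were called higher, against 8 of 10 shared genes, and 1, Khdc1a, was called lower (15.1 to 3.22 CPM); Ncr1, the restricted receptor, had 9.11 and 6.34 CPM against 2.97 and 1.94 in WT. Both the restricted and the shared list were drawn up for this test, after the results were seen. From KO to KO EAE the restricted genes had a median log2 change of -1.30 (SD 0.58) and the shared ones of 0.13 (SD 0.27). The log2 difference of -1.43 was larger than both SDs together, but these SDs are over genes and do not measure the spread between libraries. Summed per library, the shared genes had 297 and 548 CPM in KO EAE replicates 1 and 2, against 354 and 383 in KO. KO EAE replicate 1 thus lay below both KO libraries for the shared genes as well. With 2 libraries per group, the difference argues only weakly against RNA from NK cells as the whole source in KO EAE. It cannot exclude that source. None of the 8 restricted genes was called by edgeR (6 had an unadjusted p under 0.05) and several had few reads. All 8 together held 189 and 210 reads in KO EAE replicates 1 and 2. Khdc1a, at 15.1 CPM in WT, marks NK cells poorly in these sorts. Together the 8 had 12.1 and 13.5 CPM in KO EAE, 33.1 and 29.4 in KO and 25.9 and 24.4 in WT, where Khdc1a held most of the reads, and without it 9.83 and 12.7, 30.9 and 25.2, and 10.3 and 9.80 CPM. Expression of the shared genes by KO cells in EAE remains a hypothesis, untested against NK cells that lack the restricted genes and against other cytotoxic cells in the sort. RNA from macrophages and other cells, considered above for the macrophage markers, was not tested as a source of NK list genes such as Fcer1g.

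Same-named libraries differed between the deposited tables. A different way of counting the same libraries is argued against: across 8529 genes, which are not independent, the difference between replicates 1 and 2 correlated between the tables at -0.0957 in WT and -0.122 in KO (Spearman), where random parts of the same libraries reached 0.518 to 0.892. Replicate numbers exchanged within a group are argued against by the same values, since an exchange would turn the sign and keep the size. Xist in WT replicate 2, the value first noticed, was 56.3 times as high in the normalized as in the count table, where the other 3 ratios were 0.109 to 0.226. That the tables come from separate sets of libraries may account for these values, and no biological explanation was tested.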
